A study of Bos taurus with 21 samples.

How the data were processed

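Small RNA was sequenced from extracellular vesicles (EVs), the membrane-bound particles that cells release, isolated from the serum of 21 cows: 7 healthy cows, 7 with subclinical mastitis and 7 with clinical mastitis. Per the labels' protocols, RNA was extracted with the miRNeasy Mini kit and 3 µg of total RNA entered libraries made with the TruSeq small RNA kit. Bowtie and edgeR are named without a role or version, per the submitters' processing notes, which also name the ARS-UCD1.2 genome build. How vesicles were isolated, how reads were trimmed and how miRNAs were counted is not given in the sources used here.

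The authors deposited 1 table with 847 rows, each a miRNA, and a value per cow. Of the rows, 298 carry a known bovine miRNA name and 549 carry only a number behind a chromosome name. The numbered rows come without sequence, so no gene name was given to them. Of these, 67 had values equal to those of another numbered row in all 21 samples, and such rows are not independent. Family members with near-identical sequences, such as those of let-7, are reported as the authors counted them. The labels' descriptions tie each column to 1 cow. The columns of the replicate 7 cows are numbered 9 (healthy), 8 (subclinical) and 10 (clinical) in the table, and no label says why. The deposited group means equalled the means of their samples to within 4.3e-07 and were not used further.

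The deposited values are a signal in reads per 1000000, which the authors scaled separately for the known and the numbered rows. Summed over a sample, the known rows exceeded 1000000 by 2.06 to 5.39% and the numbered rows by 8.71 to 18.4%, so the values were treated as a signal and not as TPM. Within each sample and row block, 10115 of 10115 values above 0 (100%) were whole multiples of 1 step to within 0.05 reads, and whole reads were recovered from that step. The planned test had been written for TPM on a single scale; it was kept as the main test, since it needs only a non-negative normalized value. Count tests on the recovered reads are alternatives. Because the blocks were scaled separately, a value states the share of 1 block and not of the whole library.

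No pair of libraries was alike within sampling noise: the smallest chi-square per degree of freedom between any 2 libraries was 2.63 over known reads (p = 2.1e-06) and 5.87 over numbered reads. The recovered scaling totals ran from 1332 to 33776 reads per library for known miRNAs and from 11330 to 44607 for numbered ones. At 1332 reads, 1 read is worth 750.8 units of signal, so a known miRNA below that level could not be seen in that library. Limits for a count of 0 are 3 reads over the reads of a group, and intervals and limits cover counting error only, since PCR copies of a molecule were not told apart.

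The main test was limma with an intensity trend on log2(signal + 1), in 1 fit of all 21 samples with 3 group means and 18 residual degrees of freedom. It was two-sided, and the Benjamini-Hochberg adjusted p had to be under 0.05. Tested were the 598 miRNAs (131 known, 467 numbered) with a signal of at least 1 in at least 7 samples. A log2 change is on the log2(signal + 1) scale, where a library at 0 pulls a low miRNA far down, so large values of low miRNAs mostly count the libraries at 0. edgeR's quasi-likelihood test and DESeq2 were run on the recovered reads with size factors per row block, and adjusted over both blocks. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

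Both tests were tested on simulated data, with reads drawn from the real means and library sizes and 200 miRNAs changed 4-fold or 16-fold, in 10 simulations per comparison. For clinical versus healthy, on average 666 miRNAs were tested; limma recovered 26.8% of the 4-fold and 55.1% of the 16-fold changes with 37.6% of its calls false, and edgeR recovered 39.0% and 79.7% with 4.4% false. For subclinical versus healthy (669 tested), limma recovered 30.5% and 59.1% with 27.2% false, and edgeR 39.4% and 78.3% with 6.5% false. For clinical versus subclinical (667 tested), limma recovered 30.8% and 55.1% with 26.5% false, and edgeR 43.1% and 81.2% with 4.0% false. With no simulated change at all, limma made on average 0.2, 0.1 and 0.5 false calls in these comparisons, and edgeR 0, 0 and 0.1. The mean limma log2 change of known miRNAs was then still 0.65, 1.51 and −1.00, because the groups differ in depth. Calls by limma were therefore set beside count tests.

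Fixed before the data were examined were the tests, the groups, the alternatives, 15 miRNA lists and the rule for named miRNAs. The rule takes, per comparison, up to 10 higher and 10 lower known miRNAs with adjusted p under 0.05 and a mean signal of at least 10, smallest p first. Where fewer than 5 passed in a direction, it is filled to 5 by p. It adds all measured members of a sentinel list of blood, liver and inflammation miRNAs and the 2 members with the smallest p of each list. A miRNA outside the rule is marked in the text as chosen after its values were seen.

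The lists were erythrocyte, platelet and endothelial, myeloid, lymphoid, hepatocyte, mammary epithelial, muscle, mesenchymal and smooth muscle, neural, inflammation-responsive, mastitis literature, let-7, miR-17-92 and miR-30 family, and DLK1-DIO3 cluster. Of these, 12 had 2 or more tested members and were tested with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry. Single values per library were compared by two-sided exact permutation tests over all 3432 splits of 14 samples. The resemblance of both mastitis groups' changes was set beside 100 simulated unchanged groups that share the healthy samples, and was computed again with the healthy samples split into 3 and 4 (70 splits).

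The alternatives fixed in advance were the pseudocount, the filter, median-ratio and quantile scaling, no trend, array weights, 2-group fits, exact rank-sum tests, a replicate block, a minimum log2 change of 1 and the count tests. Added after seeing the data were a single scale for both blocks, known miRNAs alone, thinning of all libraries to 1371 known and 13033 numbered reads (20 draws), and leaving out the 3 libraries under 2000 known reads or the 3 replicate 7 libraries. Camera on recovered reads, shares of known reads per list, depth covariates, leave-one-out fits of edgeR, and means and ratios without each library were also added then. The reference gene table at hand is of another assembly (ARS-UCD2.0), so no coordinates are given.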

Results

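The data are miRNA profiles of serum EVs from 7 healthy cows, 7 cows with subclinical mastitis, in which the udder is inflamed without visible signs, and 7 cows with clinical mastitis. miRNAs are short RNAs that repress messenger RNAs, and vesicles carry them in blood. Reads summed over the known miRNAs of a library were 3015 ± 1621 in healthy cows, 16578 ± 9423 in subclinical cows and 9255 ± 11944 in clinical cows (SD, n = 7 each; 5040 in clinical cows without clinical 7). Numbered miRNAs, which have no name in the table, summed to 27136 ± 6643, 26825 ± 3645 and 42325 ± 5757 reads. The totals that the deposited values were scaled to were a little smaller, at 2904 ± 1580, 16184 ± 9211 and 9018 ± 11677 reads for known and 24037 ± 5962, 23553 ± 3422 and 38206 ± 5057 for numbered miRNAs. Signal below is reads per 1000000 of the known or of the numbered scaling total. A count such as lower in 7 of 7 gives the cows of the comparison's first-named group below (or above) the other group's mean. Single cows of both groups can still overlap.

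Depth moved with the groups. Subclinical libraries held more known reads than healthy ones (two-sided exact permutation p = 0.00233 for sums and for scaling totals; adjusted p = 0.00466 over 6 sums, and 0.0140 for totals over the added measures). The known share of both scaling totals was 37.5% ± 14.4 in subclinical, 12.0% ± 9.8 in healthy and 16.7% ± 18.5 in clinical libraries (SD, n = 7; 10.4% without clinical 7). The subclinical and healthy shares differed (exact permutation p = 0.00583, adjusted p = 0.0233), while clinical and subclinical shares did not pass (exact permutation p = 0.0396, adjusted p = 0.0951). Clinical libraries held more numbered reads than both other groups (exact permutation p = 0.00117 against each, for sums and totals; adjusted p = 0.0035 for sums and 0.0140 for totals).

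**Figure D1:**
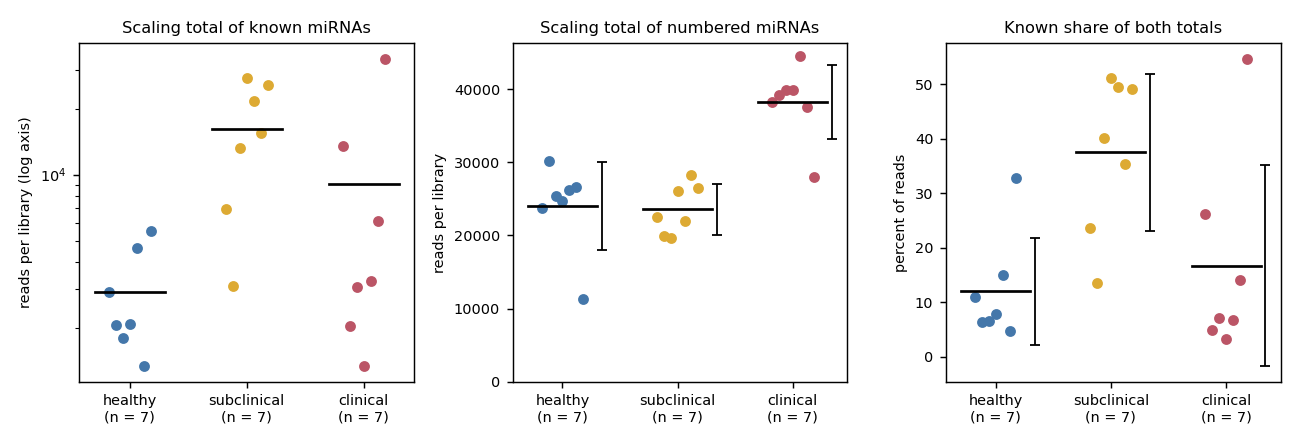
Scaling total in reads per library for known miRNAs (log axis), for numbered miRNAs, and the known share of both totals in percent, by group; points are libraries, black lines are means and bars are SD (not drawn on the log axis). Known scaling totals range from 1332 to 33776 reads per library.

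Signal was more concentrated in the top miRNAs of clinical libraries. The top 10 miRNAs took 63.1% ± 1.7 of the signal in clinical, 58.0% ± 4.0 in healthy and 56.3% ± 4.3 in subclinical cows (SD, n = 7). Both differences from clinical passed the exact permutation test (adjusted p = 0.0105 each, over 12 planned tests). The top 1 miRNA, the numbered 4_9843 in every healthy and clinical library, took 20.4% ± 1.4 in clinical and 16.1% ± 1.7 in healthy cows (exact permutation, adjusted p = 0.0070). That is a difference of 4.25 points in 1 row, against 5.12 points for the top 10. Shannon entropy was 5.30 ± 0.14 bits in clinical against 5.63 ± 0.27 in healthy (exact permutation, adjusted p = 0.0168) and 5.72 ± 0.28 in subclinical cows (exact permutation, adjusted p = 0.0105). More miRNAs were detected in subclinical (529 ± 52) than in healthy cows (438 ± 26; exact permutation, adjusted p = 0.0105), where depth also differed. Clinical cows had 478 ± 47 detected, which did not pass against healthy cows (exact permutation p = 0.0694, adjusted p = 0.119). Within the known miRNAs alone, the top 10 share did not differ between clinical cows (79.1% ± 3.0) and healthy cows (76.7% ± 6.4; exact permutation p = 0.382). The erythrocyte list took 3.20% ± 0.82, 4.40% ± 1.60 and 3.02% ± 0.66 of known reads in healthy, subclinical and clinical cows. No pair of groups passed for it (lowest exact permutation p = 0.0513, adjusted p = 0.103). Most of its reads were of miR-25, miR-486 and miR-92a (822, 284 and 282 of 1462 in subclinical 5). Of these, miR-25 and miR-92a are also on the miR-17-92 list, so red cell lysis cannot be judged from this share.

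Clinical versus healthy asked which vesicle miRNAs differ in cows with clinical mastitis. Known miRNAs did not pass in this comparison with all libraries. miR-574 had a signal of 13348 ± 9319 in clinical and 24122 ± 14836 in healthy cows (SD, n = 7), lower in 6 of 7, with a limma log2 change of −1.01 (SE 0.56, adjusted p = 0.820). let-7c, of the tumour-suppressive let-7 family, had 13432 ± 3625 against 20591 ± 8629, lower in 7 of 7 (limma, −0.56, adjusted p = 0.702). miR-2478 had 2039 ± 1798 against 9914 ± 12028, lower in 7 of 7 (limma, −1.88, adjusted p = 0.533; edgeR −1.97, adjusted p = 0.147). edgeR passed it without healthy 7 (−2.54, adjusted p = 0.0476), while without healthy 2 the ratio of means went from 4.86 to 2.85. miR-27b was read in 4 of 7 clinical libraries (262 ± 313, or 170 without clinical 6) and in none of the healthy ones, at 0 of 21103 known reads, which allows a share of up to 0.0142% (limma adjusted p = 0.533). miR-143, a smooth muscle miRNA, had 162 ± 225 in healthy (96.3 without healthy 3) and 0 of 64783 known reads in clinical cows, which allows a share of up to 0.00463% (limma adjusted p = 0.814). miR-215, abundant in liver and gut epithelium, had 14.8 ± 28.3 in clinical and 1332 ± 2278 in healthy cows (743 without healthy 7 and 811 without healthy 3). These means rest on 2 clinical reads and on 35 healthy reads, all in healthy 3 and healthy 7. For miR-215 the values by test follow. Its edgeR change was −4.51 (adjusted p = 0.0764; limma −1.89, adjusted p = 0.884), and edgeR passed it without healthy 5 (−5.16, adjusted p = 0.0394).

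In that comparison limma called 0 of 598 miRNAs, with 37 at an unadjusted p under 0.05, while edgeR called 1 and DESeq2 called 2. The edgeR call was the numbered 4_9843, named after its values were seen, the most abundant numbered row of those named here. Its signal was 435279 ± 29258 in clinical and 349408 ± 34167 in healthy cows (SD, n = 7), higher in 7 of 7 (edgeR log2 change 0.63, adjusted p = 0.0348; DESeq2 adjusted p = 0.0522; limma 0.32, adjusted p = 0.533), with the same change of 0.63 but adjusted p = 0.238 in edgeR on 1 scale for both row blocks. edgeR called 0 miRNAs without healthy 1, healthy 4 or any 1 of clinical 1 to 5, and 4 without healthy 5, clinical 6 or clinical 7. It called 2 without healthy 7.

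Subclinical versus healthy asked the same of cows inflamed without visible signs. miR-574 fell from 24122 ± 14836 in healthy to 4565 ± 3256 in subclinical cows (SD, n = 7), 5.28-fold and in 7 of 7 (limma log2 change −2.37, SE 0.56, adjusted p = 0.0289; edgeR adjusted p = 0.00727). miR-2478 fell from 9914 ± 12028 to 848 ± 389, 11.7-fold and in 7 of 7 (limma −2.75, SE 0.69, adjusted p = 0.0449; edgeR adjusted p = 0.00342), and 6.84-fold without healthy 2. DESeq2 passed both (adjusted p = 0.026 and 0.000315), but in edgeR on 1 scale for both row blocks neither passed (−0.37 and −1.15, adjusted p = 0.610 and 0.332), nor did limma with median-ratio scaling, at changes of −2.10 and −2.48 (adjusted p = 0.0859 and 0.0793). By limma only, let-7c fell from 20591 ± 8629 to 9951 ± 2236 in 7 of 7 (−0.97, SE 0.25, adjusted p = 0.0449), while edgeR gave −0.46 (adjusted p = 0.665; DESeq2 adjusted p = 0.274) and 1.21 on 1 scale (adjusted p = 0.263). miR-2431-3p rose by limma from 25.7 ± 68.1 to 488 ± 408 in 7 of 7 (7.44, SE 1.65, adjusted p = 0.0173), while edgeR gave 3.45 (adjusted p = 0.199; DESeq2 adjusted p = 0.381); its healthy value rests on 1 read, in healthy 7. Of the 21 limma fits without 1 library, miR-574 passed in 13 (highest adjusted p = 0.0875, without healthy 1), miR-2478 in 7 (0.105, without healthy 3), let-7c in 5 (0.108, without healthy 1) and miR-2431-3p in 21. At equal reads in all libraries (20 draws), limma passed miR-574 in 7 draws and miR-2478 in 0, while edgeR passed them in 16 and 15. The miR-2478 signal of healthy 7 (900.9) lay within the range of the subclinical cows (456.3 to 1438).

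miR-122, the most abundant miRNA of hepatocytes, and miR-1246 rose by edgeR but did not pass limma, and miR-122 did not pass DESeq2 (adjusted p = 0.169; miR-1246 0.0131). On 1 scale for both row blocks edgeR lost miR-122 (4.48, adjusted p = 0.0662) and passed miR-1246 (3.59, adjusted p = 0.000129). miR-122 had 11473 ± 9982 in subclinical and 1090 ± 1761 in healthy cows (SD, n = 7), 10.5-fold higher and above the healthy mean in 6 of 7 (edgeR 3.76, adjusted p = 0.00117; limma 8.06, adjusted p = 0.0849), and 20.8-fold higher without healthy 7. miR-1246, which can also be a fragment of a small nuclear RNA, had 192744 ± 158785 against 49803 ± 24589, higher in 6 of 7 (edgeR 2.37, adjusted p = 0.000841; limma 1.58, adjusted p = 0.205). Of the numbered rows, 3_6921 rose from 495 ± 872 to 10004 ± 9300 and 7_15338 from 425 ± 874 to 9829 ± 9186 (SD, n = 7), each in 7 of 7 (limma adjusted p = 0.0162 for both; edgeR adjusted p = 0.00727 and 0.0125). Both rows were named after their values were seen, and their reads were nearly equal (1601 and 1574 in subclinical cows), so they are not independent. Without healthy 7 the ratio of means went from 20.2 to 55.4 for 3_6921 and from 23.1 to 99.6 for 7_15338.

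For subclinical versus healthy, limma called 12 miRNAs (9 higher, 3 lower; 4 of them known), edgeR 10 (8 higher, 2 lower) and DESeq2 10, with 7 shared by limma and edgeR. Median-ratio scaling left 6 limma calls (6 higher, 0 lower), and edgeR with 1 scale for both blocks also called 6 (6 higher, 0 lower). Without a trend limma called 8 (8 higher, 0 lower), and without a filter 8 (7 higher, 1 lower). Without the 3 libraries under 2000 known reads (healthy 3, healthy 6 and clinical 4), a choice made after seeing the data, limma called 0 miRNAs and edgeR 6; there miR-574 had a limma change of −2.42 (adjusted p = 0.132) and an edgeR adjusted p of 0.0151. Single libraries left out took limma's count from 6 (without healthy 1, healthy 4 or subclinical 6) to 33 (without healthy 7), with 7 without healthy 2, healthy 6, subclinical 3, subclinical 5 or any 1 of clinical 1 to 4. edgeR called 27 (23 higher, 4 lower) without healthy 7, and lost miR-574 without healthy 1 (adjusted p = 0.0856) and miR-2478 without healthy 2 (adjusted p = 0.125). Without the replicate 7 libraries of all groups, whose columns are numbered differently in the table, limma called 33 (28 higher, 5 lower) and edgeR 34 (28 higher, 6 lower), also a choice made after seeing the data. The median log2 change of known miRNAs was 2.23 as deposited, 2.44 with median-ratio scaling, 1.78 with quantile scaling, 0.58 in edgeR and 1.90 in edgeR with 1 scale, and the changes above stand against that shift.

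Clinical versus subclinical asked how the 2 forms of mastitis differ. miR-122 fell from 11473 ± 9982 in subclinical to 735.5 ± 1178 in clinical cows (SD, n = 7), 15.6-fold and in 7 of 7 (limma −8.35, SE 2.34, adjusted p = 0.0446; edgeR −4.58, adjusted p = 0.00018). The fold was 25.6 without clinical 2 or clinical 5, and limma passed miR-122 in 11 of 21 fits without 1 library (highest adjusted p = 0.117, without subclinical 3), edgeR in 21. By edgeR, other hepatocyte miRNAs fell with it: miR-192 from 3777 ± 2533 to 369 ± 550 (10.2-fold; −3.86, adjusted p = 0.0034) and miR-215 from 1937 ± 1039 to 14.8 ± 28.3 (−5.52, adjusted p = 0.00212), each in 7 of 7. Without clinical 4 the miR-192 fold was 20.9. miR-215 had 188 reads in subclinical and 2 in clinical cows, 1 in clinical 1 and 1 in clinical 7. The size of its ratio of means is thus poorly known, and it went from 131 to 393 without clinical 1. miR-192 was named after its values were seen, and both miRNAs are also abundant in gut epithelium and kidney. miR-885 had 204 ± 265 in subclinical cows and 0 of 64783 known reads in clinical cows, which allows a share of up to 0.00463% (edgeR adjusted p = 0.0281, but 0.0691 without subclinical 3, 0.0731 without clinical 1 and 0.0966 without clinical 7). limma did not pass miR-192 (adjusted p = 0.121), miR-215 (0.0571) or miR-885 (0.0818). DESeq2 passed miR-122 (adjusted p = 0.0191), miR-192 and miR-215 (0.00229 each) but not miR-885 (0.543).

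miR-1246 fell by edgeR from 192744 ± 158785 to 47767 ± 28388 (SD, n = 7), 4.04-fold and in 7 of 7 (−2.25, adjusted p = 0.000414; limma adjusted p = 0.102). miR-423-5p fell by edgeR from 28771 ± 24213 to 10276 ± 3089 in 7 of 7 (−1.72, adjusted p = 0.00574), but not without subclinical 3 (−1.11, adjusted p = 0.105) or on 1 scale (−2.40, adjusted p = 0.0636). miR-12034, named after its values were seen, fell by edgeR from 5469 ± 6352 to 199.7 ± 271 in 7 of 7 (−5.26, adjusted p = 0.00018), with a ratio of means of 27.4, or 44.2 without clinical 3. miR-143 had 181 ± 168 in subclinical cows and the same 0 of 64783 reads in clinical cows (edgeR adjusted p = 0.0287), and did not pass without subclinical 3, clinical 1, clinical 6 or clinical 7 (edgeR adjusted p = 0.0759 without clinical 1). The remaining known edgeR calls, named after their values were seen, were miR-193a-5p and miR-184. miR-193a-5p was below its subclinical mean in 7 of 7 (46.5 ± 123 against 1332 ± 1829, edgeR −4.65, adjusted p = 0.0228), though subclinical 2, 4 and 7 had 0 reads of it. miR-184 was above its subclinical mean in 3 of 7 (1354 ± 2599 against 55.8 ± 61.4, edgeR 3.84, adjusted p = 0.0398). miR-193a-5p did not pass without subclinical 1 (edgeR adjusted p = 0.107), subclinical 3, clinical 1 or clinical 7, and all its clinical signal lay in clinical 6; its ratio of means went from 28.6 to 17.9 without subclinical 1. miR-184 did not pass without any 1 of healthy 5, subclinical 2, 3, 5 or 6 and clinical 3 or 5, and without clinical 3 its change was 2.12 (edgeR adjusted p = 0.494) and its ratio of means went from 24.3 to 7.78. On 1 scale edgeR gave miR-184 a change of 1.93 (adjusted p = 0.420). DESeq2 did not pass miR-143 (adjusted p = 0.502), miR-193a-5p (0.360) or miR-184 (0.157). miR-2431-3p fell by limma from 488 ± 408 to 101.5 ± 177 in 7 of 7 (−6.09, SE 1.65, adjusted p = 0.0380; edgeR −1.43, adjusted p = 0.555; DESeq2 adjusted p = 0.521). It passed limma in 11 of 21 fits without 1 library, and its ratio of means went from 4.81 to 9.90 without clinical 7.

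Numbered rows made up most calls here (22 of 24 by limma, 28 of 38 by edgeR), but also most of the tested rows (467 of 598). The row 3_6921 fell from 10004 ± 9300 to 71.6 ± 65.6 (SD, n = 7), 140-fold and in 7 of 7 (limma −6.65, SE 1.22, adjusted p = 0.00274; edgeR adjusted p = 0.000273). In the other direction 4_9843 rose from 347169 ± 42886 to 435279 ± 29258 in 7 of 7 (limma 0.33, SE 0.09, adjusted p = 0.0411; edgeR adjusted p = 0.0032), passing in 10 of 21 limma fits and 21 of 21 edgeR fits without 1 library. limma called 24 miRNAs (1 higher, 23 lower; 2 known), edgeR 38 (3 higher, 35 lower; 10 known) and DESeq2 33, with 21 shared by limma and edgeR. Fitted on the known miRNAs alone, limma called 0 of them (24 at an unadjusted p under 0.05) and edgeR 10. Without the 3 libraries under 2000 known reads limma called 18 and edgeR 33, with miR-122 at −7.62 (adjusted p = 0.0966) by limma and −4.46 (adjusted p = 0.000692) by edgeR. limma's count went to 16 without subclinical 1 or subclinical 3, and edgeR's to 25 without subclinical 3. Without the replicate 7 libraries limma called 34 (2 higher, 32 lower) and edgeR 45 (7 higher, 38 lower).

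**Figure D2:**
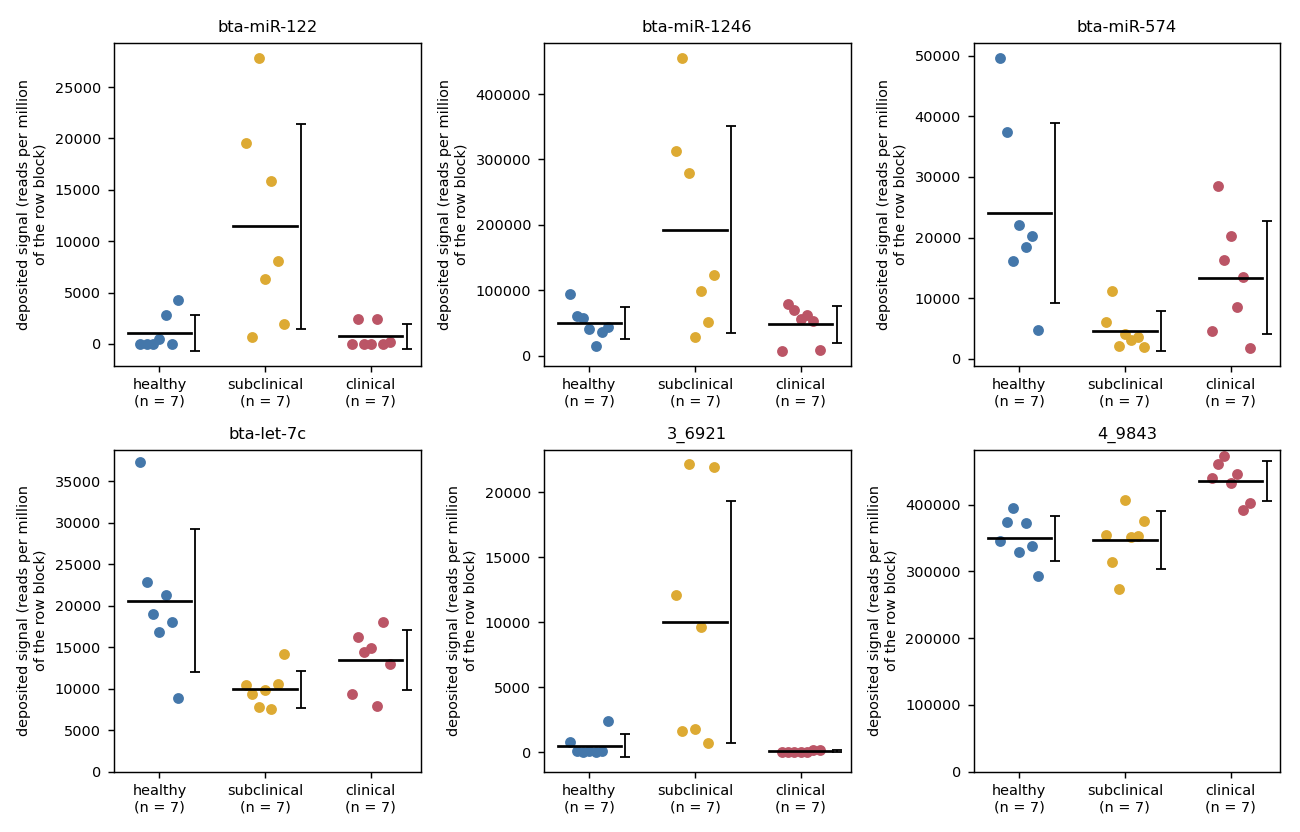
Deposited signal (reads per 1000000 of the known or numbered reads) of 4 known and 2 numbered miRNAs in each library, by group; points are libraries, black lines are means and bars are SD (n = 7). miR-122 and 3_6921 have their highest mean in subclinical cows (11473 and 10004), miR-574 and let-7c have theirs in healthy cows (24122 and 20591, let-7c by limma only), and 4_9843 in clinical cows (435279).

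The overall test of the 3 group means called 19 miRNAs by limma's moderated F test (2 known, 17 numbered), 39 by edgeR (9 known) and 34 by DESeq2, with 17 shared by limma and edgeR. Leaving out 1 library took limma's count from 5 (without subclinical 1 or subclinical 5) to 34 (without healthy 7), with 6 to 11 without subclinical 3 or any 1 of clinical 1, 2, 3, 4 or 6, and edgeR's to 25 without subclinical 3. Quantile scaling left 7 limma calls. Without the 3 libraries under 2000 known reads, limma called 5 and edgeR 22. Without the replicate 7 libraries limma called 38 and edgeR 52.

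The hepatocyte list was fixed as 8 miRNAs, of which 6 were tested. In clinical against subclinical cows all 6 had a lower value by edgeR (median log2 change −3.99; −3.02 from pooled reads with miR-885 at its limit). edgeR called 4 lower over all miRNAs and 5 adjusted over the list alone; limma called 1 and 5. camera called the list lower (adjusted p = 0.00181), but gave adjusted p = 0.146 with an estimated correlation. In subclinical against healthy cows limma called 0 members over all miRNAs and 4 higher adjusted over the list alone, and edgeR 1 and 2. camera called the list higher (adjusted p = 0.00876), with adjusted p = 0.194 with an estimated correlation. From pooled reads its median log2 change was only 0.52 there, with miR-194 at −0.83, miR-215 at −0.03 and miR-483 at 0.06. Members took 0.409% ± 0.528, 1.77% ± 1.19 and 0.132% ± 0.114 of the known reads in healthy, subclinical and clinical cows (SD, n = 7). The healthy mean was 0.229% without healthy 7, which alone had 1.49%. Clinical against subclinical had an exact permutation p = 0.00233 (adjusted p = 0.105 over 45 tests), and subclinical against healthy an exact permutation p = 0.0169 (adjusted p = 0.254; unadjusted 0.00758 without healthy 7). Without miR-122 the clinical and subclinical shares were 0.0611% ± 0.0722 and 0.654% ± 0.387 (exact permutation p = 0.0035), and the clinical mean was 0.0351% without clinical 4. The healthy share was then 0.303% ± 0.391 (exact permutation p = 0.125 against subclinical), or 0.176% without healthy 7 (exact permutation p = 0.0251), and without subclinical 7 that p was 0.046. The known share of reads moved with the list, at 37.5% in subclinical and 16.7% in clinical libraries (10.4% without clinical 7). In clinical against healthy cows neither limma nor edgeR called a member over all miRNAs (1 lower by edgeR adjusted over the list alone), and camera did not pass on the deposited scale (adjusted p = 0.546). On recovered reads camera called the list lower there (adjusted p = 0.0338; 0.241 with an estimated correlation), and from pooled reads all 6 members were lower, with miR-885 at its limit (median −2.34). The clinical and healthy shares without miR-122 had an exact permutation p = 0.081, and 0.046, 0.0361 and 0.0355 without healthy 1, healthy 2 or healthy 4.

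The let-7 family, 10 tested members, made up 41.9% ± 2.8 of known reads in healthy, 29.9% ± 9.1 in subclinical and 41.2% ± 8.5 in clinical cows (SD, n = 7). The subclinical share was lower than the healthy one at an exact permutation p = 0.00524 (adjusted p = 0.118), which did not pass. Against clinical cows it did not pass either (exact permutation p = 0.0280, adjusted p = 0.315, and unadjusted 0.0641 without clinical 7). let-7a-5p had 181765 ± 10033 in healthy and 127520 ± 42747 in subclinical cows, lower in 7 of 7 (limma −0.58, adjusted p = 0.131). let-7f had 119692 ± 13431 and 79712 ± 35687, lower in 6 of 7 (limma −0.72, adjusted p = 0.160). limma called 1 member lower in subclinical than healthy cows, and 3 adjusted over the list alone; the median log2 change was −0.35 on the deposited scale and −0.28 from pooled reads. In edgeR it was 0.27, below the 0.58 of all known miRNAs, and no member passed (0 also adjusted over the list alone). camera called the family lower (adjusted p = 0.00298; adjusted p = 0.194 with an estimated correlation). In clinical against subclinical cows limma called 0 members and 2 higher adjusted over the list alone, and edgeR 0 and 0 (medians 0.25 by limma, 0.02 by edgeR), and camera called the family higher (adjusted p = 0.0115; adjusted p = 0.393 with an estimated correlation). In clinical against healthy cows camera gave adjusted p = 0.546.

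**Figure D3:**
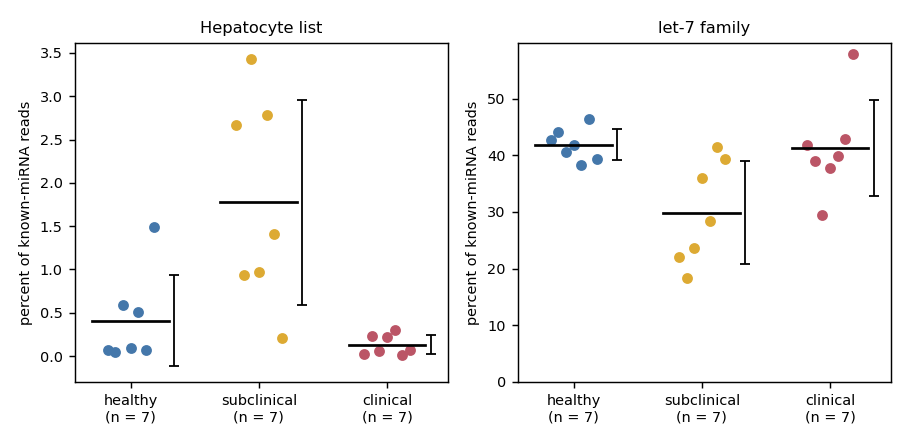
Percent of known-miRNA reads in the hepatocyte list and in the let-7 family per library, by group; points are libraries, black lines are means and bars are SD (n = 7). Means are 0.409, 1.77 and 0.132% for the hepatocyte list and 41.9, 29.9 and 41.2% for let-7 in healthy, subclinical and clinical cows.

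The other 10 tested lists did not pass camera on the deposited scale. In subclinical against healthy cows the closest were the lymphoid list (7 tested, median 2.82, adjusted p = 0.0585) and the miR-17-92 family (8 tested, median 2.76, adjusted p = 0.0585), then miR-30 (0.224), platelet and endothelial (0.348), inflammation-responsive (0.385), erythrocyte (0.504), mammary epithelial, mesenchymal and mastitis literature (0.766 each) and myeloid (0.827). Both lists passed camera with median-ratio scaling (adjusted p = 0.0361 and 0.0340) and passed fry (0.0332 and 0.0303), which tests against no change. Their medians lay near that of all known miRNAs (2.23, or 2.44 with median-ratio scaling), and among the known miRNAs alone camera gave adjusted p = 0.635 for each. On recovered reads neither passed camera (0.284 and 0.439), nor with an estimated correlation (0.281 and 0.266). Adjusted over the list alone, limma called 2 lymphoid members, 1 miR-30 member and 0 of miR-17-92 higher, and edgeR called 0, 1 and 1. In clinical against healthy cows the closest was the platelet and endothelial list (8 tested, camera adjusted p = 0.127), and in clinical against subclinical cows the mesenchymal list (3 tested, camera adjusted p = 0.557). No member of these 10 lists passed limma over all miRNAs in any comparison. edgeR called miR-143 (on the myeloid and mesenchymal lists) and miR-184 (mastitis literature) in clinical against subclinical cows. The muscle, neural and DLK1-DIO3 lists had too few tested members; in healthy, subclinical and clinical cows their shares of known reads were 0.0518, 0.0351 and 0.113% for muscle (lowest exact permutation p = 0.256), 0.0416, 0.0124 and 0.0140% for neural (0.763) and 0.0490, 0.0137 and 0.0411% for DLK1-DIO3 (exact permutation p = 0.0577, adjusted p = 0.371). These means rest on few reads: without 1 library they fell to 0.0332% (healthy 1) and 0.0183% (subclinical 5) for muscle, to 0.00292% (healthy 4), 0.00358% (subclinical 7) and 0.0084% (clinical 2) for neural, and to 0.0109% (healthy 2) and 0.00848% (subclinical 5) for DLK1-DIO3.

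Blood and inflammation miRNAs on the sentinel list did not pass limma or edgeR in any comparison, apart from miR-122 and miR-423-5p. miR-223, abundant in neutrophils, had 19103 ± 10091 in healthy, 24282 ± 11007 in subclinical and 19466 ± 6685 in clinical cows (SD, n = 7; lowest limma adjusted p = 0.665). miR-21-5p, induced in inflammation, had 16692 ± 6650, 16450 ± 6735 and 13044 ± 7595. miR-150 of lymphocytes had 14605 ± 7144, 16357 ± 5895 and 14593 ± 5914, and miR-142-5p of blood cells had 3080 ± 2489, 4098 ± 3877 and 2056 ± 1407. The red cell miRNAs miR-486 and miR-92a had 8061 ± 4068 and 6377 ± 5288 in healthy, 11983 ± 7553 and 8793 ± 4211 in subclinical, and 9012 ± 2572 and 5253 ± 2534 in clinical cows. Endothelial miR-126-3p had 6194 ± 3809, 5967 ± 3029 and 9685 ± 6151, and its partner arm miR-126-5p 195838 ± 53267, 161906 ± 110326 and 237560 ± 68486.

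Both mastitis comparisons use the same healthy cows. Across the 598 miRNAs, which are not independent replicates, their log2 changes had r = 0.339 and rho = 0.338. In simulations, 3 unchanged groups were drawn from the deviations of all 21 samples from their group means, and both comparisons shared 1 of them. They gave a mean r of 0.482 (0.102 to 0.834) and a mean rho of 0.441. The covariance was 1.10 against a simulated 1.21, and 62.0% of changes shared a sign against 66.0%. With separate healthy cows for each comparison r was −0.038 and the covariance −0.301, as means of 70 splits. Shared calls numbered 0 by limma (0 against 9 higher and 3 lower) and 0 by edgeR (1 against 8 higher; 0.013 by chance).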

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

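The tests of depth, of 1 scale for both row blocks and of the known share, for the hepatocyte list, for miR-574 and miR-2478 and for the known miRNAs as a whole, were chosen only after the result was seen; the test with miR-1246 left out was chosen before.

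Among 123 groups of 7 values, 19 held a library far from the other 6 (by the Dixon test at the 95% level), where chance flags about 1 in 20 groups if values are normally distributed. That rate does not hold for groups with libraries at 0, which were 38 of the groups and 13 of the 19, so 19 cannot be set against it. Healthy 7 held 9 of them: a numbered scaling total of 11330 reads, a known share of 32.9%, a hepatocyte share of 1.49%, and signals of 5225 for miR-192, 180.2 for miR-2431-3p, 2162 for miR-221, 1622 for miR-193a-5p and 2383 for each of 3_6921 and 7_15338. Clinical 7 had scaling totals of 33776 known and 27948 numbered reads. The columns of these libraries are numbered 9 and 10 in the table, and no label says why. Other values were miR-215 at 73.9 in clinical 1, miR-885 at 481 in healthy 4 and 760.5 in subclinical 3, miR-126-3p at 22601 and miR-184 at 6878 in clinical 3, miR-29a at 1522 in healthy 5, miR-11987 at 2445 in subclinical 1 and miR-193a-5p at 326 in clinical 6.

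The hepatocyte list was lower in clinical than in subclinical cows by camera at the preset correlation. It did not pass camera with an estimated correlation, and its share of known reads did not pass (exact permutation, adjusted p = 0.105). Known reads and known share also differed in mean between these groups. With log2 known reads as a covariate, a test of the difference in the number of known reads, 3 of the 4 edgeR calls kept an adjusted p under 0.05 and the median of the 6 members went from −3.99 to −3.94; with the known share as a covariate 3 did (−3.75); on 1 scale for both blocks, which removes the separate scaling of the known rows, 4 did (−4.82). miR-885 was lost with both covariates (edgeR log2 change −4.12, then −4.09 at adjusted p = 0.0544 and −3.93 at 0.0871); its change barely moved, and why the adjusted p rose was not tested. The values with covariates argue against depth and library yield as the whole cause. The single scale lowered the known miRNAs together, from an edgeR median of −0.36 to −1.15. A shift common to the block cannot test the separate scaling, which stays open. A hypothesis that stays open, untested here, is that EVs of subclinical cows may hold more liver-derived miRNA, or those of clinical cows less. From pooled reads the list's median log2 change against healthy cows was 0.52 in subclinical and −2.34 in clinical cows. An unlabelled batch or a difference between the animals other than mastitis stays open as well.

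miR-574 and miR-2478 fell in subclinical against healthy cows within the known reads, of which miR-1246 took a larger part. With miR-1246 left out of the scaling their mean limma log2 change was −2.28, which argues against miR-1246 as the whole cause. On 1 scale for both blocks their mean edgeR change was −0.76 (miR-574 −0.37, adjusted p = 0.610; miR-2478 −1.15, adjusted p = 0.332), against −2.01 and −2.94 on separate scales. The single scale raised the known miRNAs together, from a median of 0.58 to 1.90, and against that median both stayed low (−2.59 and −3.52 on separate scales, −2.27 and −3.05 on 1 scale). A shift common to the block cannot test the separate scaling, so it cannot be told apart from a fall of these miRNAs, and an effect of mastitis on either stays open, untested.

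Known miRNAs had a higher mean log2(signal + 1) change in subclinical against healthy cows, 2.14. At equal reads in all libraries (20 draws) that mean was 0.54, so most of the shift may come from depth, since shallow healthy libraries list low miRNAs at 0. What made the known reads of subclinical cows more numerous, in the animals or in the libraries, was not tested.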

How the results depend on the processing

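Chosen only after seeing the data were the single scale for both blocks, edgeR with a replicate block, known miRNAs alone, equal reads, the libraries left out for low reads or as replicate 7, and camera on recovered reads or known miRNAs alone; where no cause is named, the cause was not tested. Below, SvH, CvH and CvS are subclinical versus healthy, clinical versus healthy and clinical versus subclinical, with limma counts of 12, 0 and 24, and 19 for any difference. Pseudocounts 0.1 and 10, no filter, a mean of at least 10, no trend and a minimum change gave SvH 8 to 11 and CvS 19 to 26. For SvH, 9 higher and 3 lower became 8 and 0 with no trend and 7 and 1 with no filter. Depth limits the rest: at a known scaling total of 1332 reads many miRNAs are listed at 0.

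SvH went to 6 with median-ratio scaling, 24 with array weights, 5 with 2 groups only, 0 with rank-sum tests (52 at an unadjusted p under 0.05), 6 in edgeR on 1 scale, 2 with known miRNAs alone (edgeR 5, fewer miRNAs tested), 5 at equal reads, and 0 without the low libraries (edgeR 6, fewer samples). CvS went to 10 with rank-sum tests, 38 in edgeR, and 0 with known miRNAs alone (24 at an unadjusted p under 0.05; edgeR 10). CvH was 1 in edgeR, 2 in DESeq2 and 1 in edgeR at equal reads. Any difference went to 7 with quantile scaling, 29 with array weights, 39 in edgeR, 34 in DESeq2, 39 in edgeR on 1 scale, 0 with known miRNAs alone (26 at an unadjusted p under 0.05; edgeR 9), 12 at equal reads and 5 without the low libraries. Without the replicate 7 libraries limma called 0 (34 at an unadjusted p under 0.05), 33, 34 and 38 (CvH, SvH, CvS, any) and edgeR 1, 34, 45 and 52.

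Leaving out 1 library gave limma 0 calls throughout for CvH, where 37 had an unadjusted p under 0.05 with all libraries and edgeR called 0 to 4. SvH ran from 6 (healthy 1, healthy 4 or subclinical 6) to 33 (healthy 7; edgeR 27), with 7 without healthy 2, healthy 6, subclinical 3, subclinical 5 or any 1 of clinical 1 to 4. CvS ran from 16 (subclinical 1 or 3) to 29 (healthy 7). Any difference ran from 5 (subclinical 1 or 5) to 34 (healthy 7), with 6 or 7 without subclinical 3, clinical 1, clinical 2 or clinical 4, 10 without clinical 3 and 11 without clinical 6.

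As a replicate block, the shared numbers gave limma 0, 8, 23 and 20 calls (CvH, SvH, CvS, any) and edgeR 0, 11, 33 and 33. Same-numbered cows mostly did not deviate together. For CvH r ran from −0.063 to 0.315 with 2 of 7 above 0.1, for CvS from −0.086 to 0.085 with 0 and for SvH from −0.123 to 0.244 with 1. In these comparisons 1, 1 and 2 of 7 cows correlated best with their own number. The block is thus no part of the design. The highest r, 0.315, was that of clinical 7 with healthy 7, and subclinical 7 also correlated best with healthy 7 (r = 0.062).

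Lists past camera numbered 0 (CvH), 2 (SvH) and 2 (CvS). On recovered reads they were 1, 0 and 1 (the hepatocyte list for CvH and CvS), with an estimated correlation 0 and 0 for SvH and CvS, for SvH 3 by fry and 3 with median-ratio scaling, for CvS 1 by fry and 1 with median-ratio scaling, and for SvH 1 with known miRNAs alone. The hepatocyte adjusted p of 0.00876 (SvH) became 0.194 with an estimated correlation, 0.284 on recovered reads and 0.182 with known miRNAs alone; that of 0.00181 (CvS) became 0.146 with an estimated correlation and ran from 6.91e-05 to 0.00547 otherwise. The let-7 adjusted p of 0.00298 (SvH) became 0.194 with an estimated correlation, 0.124 by fry, 0.126 with median-ratio scaling and 0.590 on recovered reads; that of 0.0115 (CvS) became 0.393, 0.309, 0.231 and 0.718.

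The r of 0.339 between both mastitis changes turned to −0.04 with split healthy cows. The difference in the top 10 share of the summed signal for SvH, −1.73 points, turned to 0.916 for the top 1 miRNA. Neither passed. Of 113 named values, 112, 111 and 107 kept direction and call with pseudocount 0.1, pseudocount 10 and median-ratio scaling. Reversed, none having passed, were miR-126-3p (0.26), miR-21-5p (0.25) and miR-23a (0.04) for SvH with median-ratio scaling and miR-27b (0.18) for CvS with pseudocount 10.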

Other observations

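The counts of splits for calls were chosen only after the result was seen, as were the relations of miR-122 to numbered rows; the counts of splits for lists and the test of let-7 with miR-1246 left out were chosen before.

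Several named miRNAs had unequal means without passing limma or edgeR. miR-29a, of an antifibrotic family, had 363 ± 565 in healthy, 1580 ± 779 in subclinical and 526 ± 545 in clinical cows (SD, n = 7), above the healthy mean in 7 of 7 subclinical cows (limma 6.34, adjusted p = 0.160; edgeR 2.36, adjusted p = 0.199), and the healthy mean was 170 without healthy 5. miR-25, of the miR-17-92 family, had 16324 ± 4647, 22726 ± 9214 and 15294 ± 4522, and the clinical cows were below the subclinical mean in 7 of 7 (limma −0.53, adjusted p = 0.395). miR-221, common in endothelium, had 509 ± 801, 630 ± 401 and 726 ± 387 (limma 4.01 for clinical against healthy, higher in 6 of 7, adjusted p = 0.762), and the healthy mean was 234 without healthy 7. miR-11987 had 2787 ± 2954, 606 ± 853 and 4460 ± 5253, higher in clinical than subclinical cows in 6 of 7 (limma 3.76, adjusted p = 0.319; edgeR adjusted p = 0.0869), and the ratio of 7.35 went to 4.47 without clinical 4 and 14.9 without subclinical 1.

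For clinical versus subclinical, 1 of 100 splits of the samples, the real one, gave as many limma calls (24, highest other 17) and 1 of 100 as many edgeR calls (38, highest other 17). For any difference, 1 of 100 splits, again the real one, gave as many by limma (19, highest other 2) and 1 of 100 by edgeR (39, highest other 23). In both, chance is unlikely but not excluded, since 1 of 100 is the least that these splits could give. For subclinical versus healthy, 2 of 100 splits gave as many by limma (12, highest other 19) and 6 of 100 by edgeR (10, highest other 37). Chance is not excluded there, since by either tool another split gave more calls than the real one. Why 1 split gave 37 calls, several times the real 10, was not tested. For clinical versus healthy limma called 0 (37 at an unadjusted p under 0.05, highest other 6). Every split matches a count of 0, so the limma count cannot test chance. As many edgeR calls came in 13 of 100 splits (1, highest other 3), so chance cannot be excluded.

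Counts of lists past camera were likewise set beside 100 splits. As many lists passed in 8 of 100 splits for subclinical versus healthy (2, highest other 5). For clinical versus subclinical as many passed in 10 of 100 (2, highest other 3). Chance cannot be excluded for either count. For clinical versus healthy 0 lists passed (highest other 3), which every split matches, so that count cannot test chance.

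A hypothesis was that the smaller let-7 share of subclinical cows only mirrors their larger miR-1246 share (18.8% ± 15.5 of known reads against 4.78% ± 2.34 in healthy cows, SD, n = 7, exact permutation p = 0.0221). Among known reads other than miR-1246, let-7 took 36.3% ± 5.7 in subclinical and 44.0% ± 3.4 in healthy cows, a difference of −7.73 points (exact permutation p = 0.0140), against −12.0 points with miR-1246 (exact permutation p = 0.00524). That share did not pass over all lists (exact permutation, adjusted p = 0.118), and the edgeR median of let-7 members was 0.27, below the 0.58 of all known miRNAs. As a share of known reads, miR-1246 may account for part of the difference but not for the whole of it.

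Within groups, the numbered 3_6921 and 7_15338 were not shown to vary with miR-122 (6 relations, 7 cows each). For 3_6921, Pearson's r was 0.72 in healthy, 0.47 in subclinical and −0.21 in clinical cows (exact permutation p = 0.114, 0.281 and 0.819; adjusted p = 0.342, 0.440 and 0.819), with rho 0.26, 0.50 and 0.37 (exact permutation p = 0.571, 0.267 and 0.419; adjusted p = 0.686 each). For 7_15338, r was 0.77, 0.46 and −0.37 (exact permutation p = 0.114, 0.293 and 0.490; adjusted p = 0.342, 0.440 and 0.588), with rho 0.27, 0.32 and −0.20 (exact permutation p = 0.586, 0.498 and 0.686; adjusted p = 0.686 each). Without the 2 cows farthest from the median, r was −0.23, −0.10 and 0.45 for 3_6921 and −0.13, −0.10 and 0.26 for 7_15338, so the higher values rest on those cows.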
